A study of Homo sapiens with 9 samples.

How the data were processed

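Messenger RNA was measured by sequencing in 9 libraries of neural progenitor cells derived from H1, an established human embryonic stem cell line. Per the labels' protocols, confluent stem cells on a Matrigel coat were moved into a neural induction medium, the E2A knockout lines had been made in the stem cells with CRISPR-Cas9 editing, and libraries came from an Illumina TruSeq RNA kit. The submitters' processing notes name TopHat2 2.0.3, RSEM 1.1.20 and the genome build GRCh38, with no role or order given. How the knockout lines were picked, and the part of the gene that was edited, are not given in the sources used here. The series title also speaks of undifferentiated stem cells, which were not analysed here.

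The authors deposited 1 table of FPKM values (fragments normalized to transcript length and to all mapped fragments), per the file headers, with 18996 genes under numeric identifiers and 2 decimals. The design had been written for RPKM, the word in the table's title, and the same test fits both units. Symbols were assigned by gene identifier from a RefSeq gene table, which matched 18653 of the 18996 identifiers. Every library had a column of its own.

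FPKM values carry no read totals, so the depth of each library is unknown and no counting interval can be given. The spacing of low values, which gives relative depth where whole reads were counted, was read from 127 genes with values of at least 0.1 FPKM. The worth of 1 step relative to the mean of the libraries ran from 0.963 to 1.02. Only values close to the lowest of each gene were kept, so larger differences in depth could not show. The measure therefore does not decide whether depth differed. Values listed at 0 numbered 1692 to 1726 per library in wild type, 1033 to 1128 in knockout line 1 and 1346 to 1434 in knockout line 4. No pair of libraries held identical values.

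Libraries were grouped by the genotype and line in their titles, with 3 libraries each of wild type, knockout line 1 and knockout line 4. The labels do not say that the replicates were separate cultures, so the p-values measure the spread between these libraries, which may be technical. Genes with at least 1 FPKM in at least 3 of the 9 libraries were tested, 13610 in all. Values were transformed to log2(FPKM + 1), a pseudocount of 1, and fitted with limma 3.58.1 in R 4.3.3, using empirical Bayes moderation with an intensity trend and 1 model over the 3 groups. The contrasts were the mean of both knockout lines minus wild type, each line minus wild type, and line 4 minus line 1. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values. Levels are given as mean FPKM ± SD with n = 3, and log2 changes as estimate ± SE.

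Before the data were examined, 20 gene lists with 351 distinct symbols were fixed, of which 346 were found in the table. Lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 20 lists, and again with an estimated correlation and with fry. The genes to be named were set by a rule fixed at the same time. The rule took TCF3, then the 8 highest and 8 lowest changes among genes that passed in both lines with 1 sign and whose 6 knockout libraries lay to 1 side of the 3 wild-type libraries. It also took the 5 largest differences between the lines in each direction among genes whose libraries did not overlap, and up to 4 tested members of each list, passing members first and by size of change. Clone-based and LOC names were left out. A single gene on the Y chromosome and 4 other genes that met the rule are not reported here. Other genes named below were chosen after their values were seen, as were 6 further lists described among the other observations.

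The fit was tested on simulated data over 13610 genes for the mean of both lines against wild type. It recovered 34% of genes changed by 0.25 on the log2 scale, 96% of those changed by 0.5 and 100% of those changed by 1. Of 172 calls, 7 were false. The simulation changed 50 genes at each size, all well expressed in wild type, with independent normal noise. Far more genes were called in the real data, so these rates need not hold there or for low genes. Alternatives were another pseudocount, no filter and a stricter filter, TPM, median-of-ratios and quantile scaling, eBayes without trend and with robust fitting, the replicate number as a block, at least a 2-fold change, and leaving out each library in turn. A correction for GC content and transcript length was added after the data had been seen. Figures were drawn with matplotlib 3.10.9.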

Results

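The transcriptomes of neural progenitor cells from wild-type H1 cells and from 2 E2A knockout lines, numbered 1 and 4, were compared in 9 libraries, 3 per group. E2A is the product of TCF3, a basic helix-loop-helix transcription factor that pairs with tissue-specific partners and is held in check by ID proteins. Summed FPKM lay between 449960 and 500398 per library, and between 12530 and 13170 genes reached 1 FPKM. The 10 most abundant genes took 8.0% to 11.1% of the sum. The first principal component, with 78.5% of the variance, separated wild type from both knockout lines, and the second, with 17.5%, separated line 1 from line 4.

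**Figure D1:**
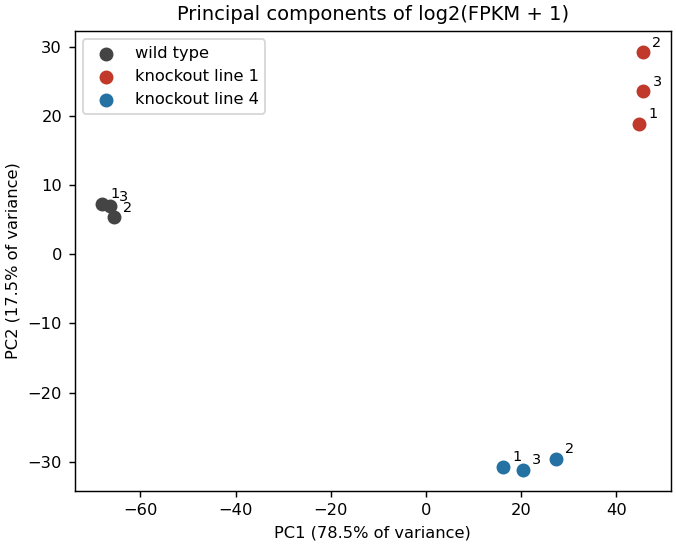
Scores of the 9 libraries on the first and second principal components of log2(FPKM + 1), coloured by group and numbered by replicate. The wild-type libraries lie between -68.1 and -65.6 on the first component, and the knockout libraries between 16.2 and 45.7.

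TCF3 (chromosome 19, 1609292 to 1652615, GRCh38) was measured first, as the targeted gene. It stood at 106.93, 105.07 and 106.09 FPKM in the 3 wild-type libraries, at 36.93, 35.8 and 38.47 FPKM in line 1, and at 49.21, 43.36 and 52.0 FPKM in line 4. The transcript therefore fell by 1.49 on the log2 scale in line 1 and by 1.13 in line 4, and remained detectable in all 6 knockout libraries. The mean change was -1.31 ± 0.05 (limma, adjusted p = 3.23e-11), with all 6 knockout libraries below the 3 wild-type libraries. An exact two-sided permutation test of the log2 values gave p = 0.0119, the smallest that the 84 splits allow. A level of mRNA does not show how much E2A protein was left.

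The main comparison asked which genes differ between wild-type and E2A knockout cells under neural induction. Most tested genes of the forebrain and eye field were lower in the knockout cells, while most genes induced by low oxygen, glycolytic genes and epithelial genes were higher. The 3 lists passed with camera at a preset correlation and not with an estimated correlation, where adjusted p = 0.173, 0.166 and 0.0828. PAX6, a transcription factor of the neural plate and eye, fell from 32.5 ± 1.1 FPKM in wild type to 0.0933 ± 0.0208 in line 1 and 0.127 ± 0.0493 in line 4. ADM, which encodes the vasodilator peptide adrenomedullin and is induced by low oxygen, rose from 0.670 ± 0.223 FPKM to 139 ± 9.13 and 136 ± 6.02. EPCAM, an epithelial adhesion molecule, rose from 22.0 ± 2.67 FPKM to 306 ± 9.40 and 277 ± 17.

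Of the 13610 genes tested, 10965 differed between the mean of both lines and wild type, with 4768 higher and 6197 lower. Of these, 2287 changed by at least 2-fold, 1338 higher and 949 lower. In 8551 genes the 6 knockout libraries did not overlap the 3 wild-type libraries, which chance gives for 2.38% of genes. The median change of all tested genes was -0.08. Rescaling to TPM moved it by -0.11, so small changes depend on the scaling.

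Among the 8 genes with the largest rise were those for the secreted proteins NPPB, a natriuretic peptide, and VGF, a neuropeptide precursor, and for the phospholipid-binding protein ANXA1. NPPB changed by 6.91 ± 0.15 on the log2 scale, ANXA1 by 6.70 ± 0.15 and VGF by 6.10 ± 0.10. Further genes of this set were ADM, at 6.38 ± 0.07, NDRG1, at 5.87 ± 0.08, the transcriptional repressor BHLHE40, at 5.85 ± 0.07, and ANKRD37, at 5.72 ± 0.09. The 8 with the largest fall were led by the imprinted gene NNAT, which went from 353 ± 11.8 FPKM to 1.16 ± 0.157 in line 1 and 0.937 ± 0.172 in line 4, a change of -7.44 ± 0.07. FEZF1, a forebrain zinc finger factor, changed by -6.07 ± 0.29. CHCHD2, a mitochondrial protein, changed by -5.78 ± 0.11, and PAX6 by -4.92 ± 0.07. LMO1, SIX3, LHX5 and SEZ6 changed by -4.79 ± 0.17, -4.43 ± 0.16, -4.20 ± 0.17 and -4.15 ± 0.14. Adjusted p for the genes given here was at most 1.73e-10 by limma, and each moved in 6 of 6 knockout libraries. NNAT lies within an intron of BLCAP and CHCHD2 has processed pseudogenes, so their levels are uncertain where reads could be split.

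**Figure D2:**
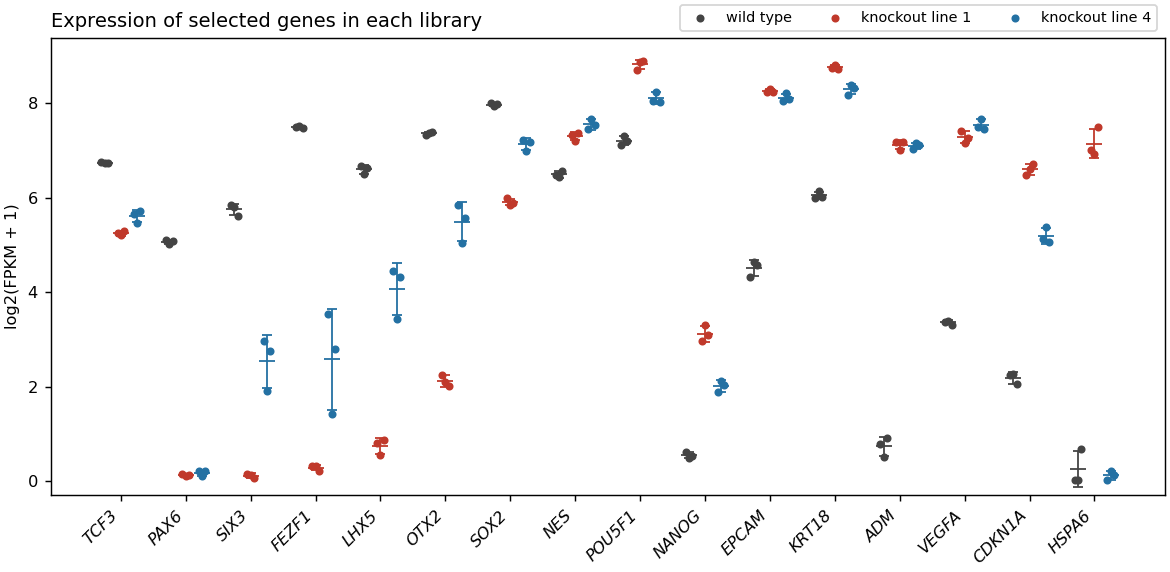
Expression of 16 genes as log2(FPKM + 1) in each of the 9 libraries, with the mean and SD of each group; SOX2, NES and POU5F1 were chosen after their values were seen. PAX6 falls below 1 FPKM in all 6 knockout libraries, and HSPA6 is high in line 1 alone, at 143 ± 32.1 FPKM.

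In the forebrain and eye field list, 8 of 9 tested genes fell and 1, FEZF2, rose, with a median change of -3.48 (camera, adjusted p = 0.00159, and adjusted p = 0.173 with an estimated correlation). The other 7 members of this list were below the filter, and with no filter the median over 16 members was -0.95. SIX3, which specifies anterior neural plate, fell from 53 ± 4.41 FPKM to 0.0800 ± 0.0361 in line 1 and 5.08 ± 2.09 in line 4. OTX2, a head organizer gene, fell from 164 ± 2.61 FPKM to 3.36 ± 0.369 and 45.1 ± 12.5. In the neural progenitor list, 12 of 14 tested genes fell and 2 rose, with a median of -1.40 (camera, adjusted p = 0.00133, and adjusted p = 0.312 with an estimated correlation). SOX21 changed by -3.50 ± 0.14, ZNF521, a zinc finger factor of early neural conversion, by -2.80 ± 0.07, and CDH2, which encodes N-cadherin, by -2.53 ± 0.10. The 2 that rose were NES, at 0.94, and SOX3, at 0.41, chosen after their values were seen. In the same libraries the hypoxia and glycolysis list had a median change of 2.30 and the p53 target list of 1.20 (adjusted p = 0.166 and adjusted p = 0.172 with an estimated correlation).

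The E protein and ID factor list, which holds TCF3 itself, fell in 7 of 7 members with a median of -1.16 (camera, adjusted p = 0.00159, and adjusted p = 0.173 with an estimated correlation). ID2 fell from 102 ± 4.27 FPKM to 24.1 ± 2.42 in line 1 and 9.76 ± 1.35 in line 4. ID1 changed by -1.40 ± 0.16 and ID4 by -1.16 ± 0.08. The other E protein genes, TCF4 and TCF12, named after their values were seen, changed by -0.80 and -0.95.

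Neuronal and pluripotency genes moved both ways. Of 10 tested neuronal genes, 3 rose and 7 fell. The 3 were the neurofilament genes NEFL, at 3.07 ± 0.07, and NEFM, at 2.54 ± 0.08, and the RNA-binding protein gene ELAVL3, at 2.12 ± 0.08. MAP2, a dendritic microtubule protein, changed by -1.75 ± 0.13. The median of this list was -0.66 and its mean 0.09, and camera gave adjusted p = 0.549. The median was 0.03 over 22 members with no filter and -0.27 over 7 with a mean of at least 5 FPKM. Of 12 tested pluripotency genes, 5 rose and 7 fell (camera, adjusted p = 0.757). NANOG, a core pluripotency factor, rose from 0.460 ± 0.0656 FPKM to 7.71 ± 1.04 in line 1 and 3.04 ± 0.325 in line 4, and UTF1 changed by 1.51 ± 0.10. POU5F1, another core factor, named after its values were seen, rose from 147 FPKM to 454 and 276. SALL4 and ZFP42, which also mark stem cells, changed by -2.03 ± 0.07 and -2.26 ± 0.09. The midbrain, hindbrain and spinal cord list had 5 tested genes, 3 higher and 2 lower (camera, adjusted p = 0.545). GBX2, a hindbrain boundary factor, changed by 2.29 ± 0.07 and PAX2, a midbrain boundary factor, by -2.29 ± 0.07, and in each case the higher group was below 5 FPKM.

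Epithelial genes rose. In the non-neural and surface ectoderm list, 14 of 15 tested genes rose and 1, KRT7, fell, with a median of 1.08 (camera, adjusted p = 5.51e-06, and adjusted p = 0.0828 with an estimated correlation). The median was 1.91 with a pseudocount of 0.1 and 1.73 over the 9 members with a mean of at least 5 FPKM. Beside EPCAM, the simple-epithelium keratins KRT18, KRT8 and KRT19 changed by 2.48 ± 0.05, 2.20 ± 0.05 and 1.99 ± 0.06. KRT8 and KRT18 have many pseudogenes, which makes their levels uncertain. In the mesenchyme and extracellular matrix list, 12 of 16 rose and 2 fell (camera, adjusted p = 0.00146, and adjusted p = 0.131 with an estimated correlation). TAGLN, an actin-binding protein, rose from 11.6 ± 1.83 FPKM to 291 ± 4.85 in line 1 and 116 ± 22.6 in line 4, and LOX, which cross-links collagen, changed by 2.79 ± 0.08. ZEB2, a transcriptional repressor also active in neural cells, went the other way, at -3.84 ± 0.11.

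For the mean of both lines, the endoderm list rose in 7 of 7 tested genes (camera, adjusted p = 0.00269, and adjusted p = 0.109 with an estimated correlation). The chemokine receptor gene CXCR4, which is not restricted to endoderm, rose from 2.91 ± 0.0802 FPKM to 24.0 ± 1.90 and 16.6 ± 2.49. FOXA3 and HHEX, named after their values were seen, did not pass in line 1, at -0.10 and -0.03, and rose in line 4, by 0.53 and 1.02. APOA1 and PRDM1 stayed below 2 FPKM in each group mean. In the neural crest list, 8 of 11 rose and 2 fell (camera, adjusted p = 0.0191, and adjusted p = 0.131 with an estimated correlation). ETS1, SNAI2 and NGFR changed by 2.68 ± 0.09, 2.46 ± 0.11 and 2.19 ± 0.08. This call was lost with no filter, at adjusted p = 0.371, with a mean of at least 5 FPKM, at 0.309, with quantile normalization, at 0.0527, and with the GC and length correction, at 0.0535. The primitive streak and mesoderm list had 4 tested genes, of which KDR, WNT3 and MIXL1 rose, by 0.93 ± 0.08, 0.55 ± 0.08 and 0.50 ± 0.09, and TBX6 gave -0.04 ± 0.09 (camera, adjusted p = 0.141). With no filter that list passed, at adjusted p = 0.0489. MIXL1 did not pass with quantile normalization.

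For the mean of both lines, most tested genes of stress, cell cycle arrest and glycolysis rose, and most proliferation genes fell. In the hypoxia and glycolysis list, 18 of 19 genes rose and 1, EGLN3, did not pass (camera, adjusted p = 1.58e-10, and adjusted p = 0.166 with an estimated correlation). VEGFA, the vascular growth factor gene, rose from 9.28 ± 0.306 FPKM to 155 ± 14.2 in line 1 and 187 ± 14.9 in line 4. In the stress and immediate early list, 16 of 17 rose and 1, HSP90AA1, fell, with a median of 2.12 (camera, adjusted p = 1.79e-07, and adjusted p = 0.0828 with an estimated correlation). DDIT3 and TRIB3, of the endoplasmic reticulum and amino acid stress responses, changed by 4.4 ± 0.10 and 4.34 ± 0.11, and ASNS, asparagine synthetase, by 4.11 ± 0.08. The p53 targets rose in 14 of 16 genes and fell in 1, XPC, which did not pass with median-of-ratios or quantile scaling (camera, adjusted p = 2.77e-06, and adjusted p = 0.172 with an estimated correlation). CDKN1A, which encodes the cell cycle inhibitor p21, rose from 3.56 ± 0.373 FPKM to 96.2 ± 8.18 and 35.8 ± 4.37. In the CDK inhibitor and cyclin D list, 7 of 9 rose and 1 fell, or 2 with TPM or quantile scaling (camera, adjusted p = 0.00496, and adjusted p = 0.131 with an estimated correlation), among them CCND2 at 1.78 ± 0.05. For the mean of both lines, the proliferation list fell in 21 of 22 genes, and CCNE1 did not pass, with a median of -0.89 (camera, adjusted p = 9.87e-07, and adjusted p = 0.172 with an estimated correlation). PLK1, a mitotic kinase, changed by -2.16 ± 0.05, MKI67 by -2.12 ± 0.08, and TOP2A, the topoisomerase of dividing cells, by -2.09 ± 0.07.

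Signalling lists did not move 1 way. The BMP list had 8 members higher and 10 lower of 18 (camera, adjusted p = 0.960). BMP2, a ligand, changed by -2.55 ± 0.07, while NOG, a secreted BMP antagonist, and BAMBI, a decoy receptor, changed by 2.31 ± 0.08 and 2.34 ± 0.07. The WNT list had 8 higher and 10 lower of 19 (adjusted p = 0.545), and 5 higher and 11 lower with quantile normalization. The secreted antagonists FRZB and SFRP1 changed by -3.40 ± 0.17 and -1.79 ± 0.09, and the receptor FZD5 by -2.18 ± 0.08. The Nodal and activin list had 4 higher and 7 lower of 11 (adjusted p = 0.757). FST, which encodes the activin antagonist follistatin, changed by -2.19 ± 0.09. The Notch list had 7 higher and 5 lower of 15 (adjusted p = 0.316), with HES4 at 3.81 ± 0.09 and the fringe gene MFNG at -1.61 ± 0.10. In total, 12 of 20 lists passed, 8 higher and 4 lower. None passed with an estimated correlation, where the lowest adjusted p was 0.0828. Adjusted over the list alone, the numbers of members higher and lower equalled those over all genes tested in each of the 20 lists.

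**Figure D3:**
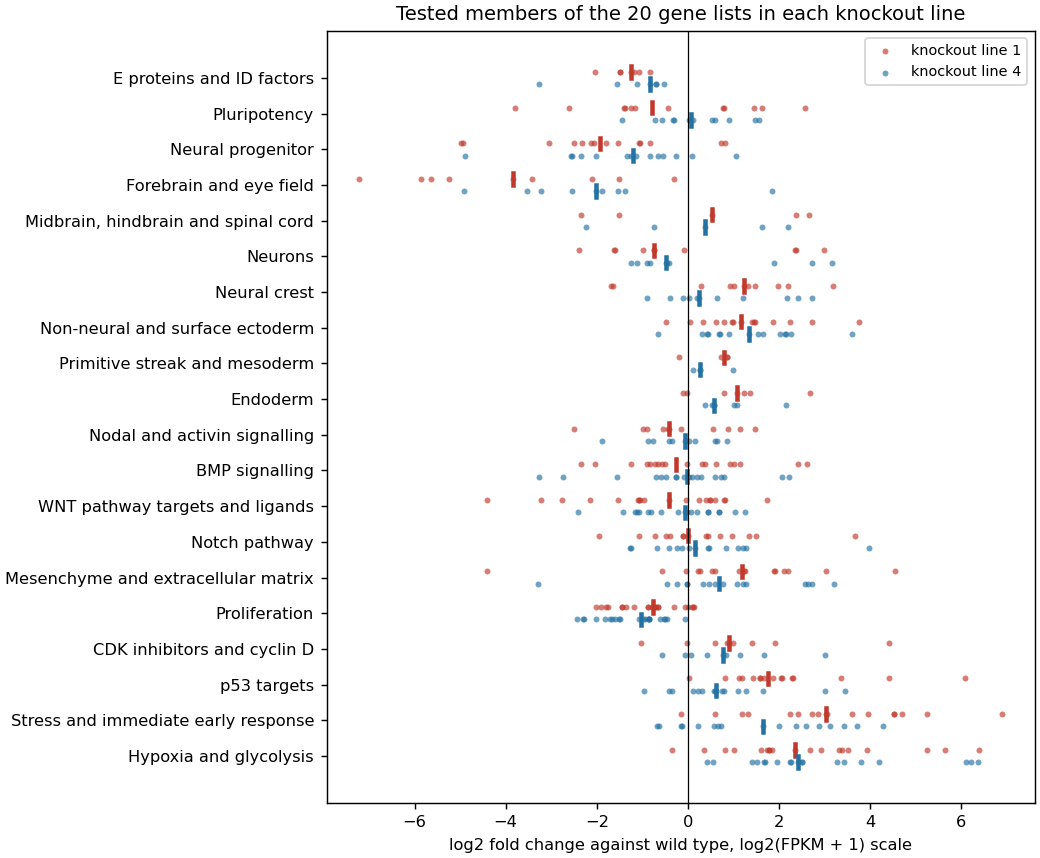
Log2 fold change against wild type, on the log2(FPKM + 1) scale, of each tested member (point) of the 20 gene lists in line 1 and line 4, with bars at the list medians. The forebrain and eye field list has its median at -3.84 in line 1 and -2.01 in line 4, and the hypoxia and glycolysis list at 2.36 and 2.42.

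Each line was also set against wild type alone. In line 1, 10837 genes differed, 4965 higher and 5872 lower, and in line 4, 10462, with 4349 higher and 6113 lower. The forebrain list fell in 9 of 9 genes in line 1 and in 8 of 9 in line 4, where FEZF2 rose by 1.85. Hypoxia and glycolysis genes rose in 18 of 19, with EGLN3 lower, and in 19 of 19. Proliferation genes fell in 17 of 22 in line 1, where PCNA, RRM2, TYMS, E2F1 and CCNE1 did not pass, and in 21 of 22 in line 4. Stress genes rose in 16 of 17 in line 1, with 1 lower, and in 13 of 17 in line 4, with 2 lower. HSPA1A, higher in the mean of both lines, changed by 2.73 in line 1 and -0.67 in line 4. The p53 targets rose in 15 of 16 in line 1 and in 12 of 16 in line 4, with 3 lower in line 4. In line 1, 12 lists passed, 8 higher and 4 lower, and in line 4, 11 passed, 7 higher and 4 lower; none did in either line with an estimated correlation, where the lowest adjusted p was 0.0817 and 0.0837. Neural crest genes, at adjusted p = 0.0169 in line 1 and 0.0549 in line 4, made up this difference in number, and the test of the difference between the lines gave adjusted p = 0.704.

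Genes that passed in both lines with the same sign numbered 8314, of which 3535 were higher and 4779 lower. Independent lists of these sizes would share 1586.54 higher and 2637.44 lower genes. Another 540 genes passed in both lines with opposite signs. Across genes, which are not independent replicates, the log2 changes of the lines had a correlation of 0.853, and 81.9% had the same sign. Simulated groups with no effect that shared their controls gave a correlation of 0.501, 66.7% of the same sign and 0 shared calls on average. The covariance was 0.679, against 0.00485 in the simulation. The simulation argues against the spread between the shared control libraries as the source of the excess overlap. It did not vary what all 3 wild-type libraries have in common, and they are too few to be split. Part of the excess may come from that.

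The lines differed from each other in single stress, p53 and forebrain genes, and no list difference passed with an estimated correlation, where the lowest adjusted p was 0.253. HSPA6, a strictly inducible heat shock chaperone, stood at 143 ± 32.1 FPKM in line 1, at 0.0900 ± 0.0700 in line 4 and at 0.217 ± 0.341 in wild type. CYP26A1, which degrades retinoic acid, stood at 1.84 ± 0.175 FPKM in line 1, 48.4 ± 6.44 in line 4 and 63.1 ± 1.92 in wild type. Of 9 forebrain genes, 6 were higher in line 4 than in line 1 and none was lower (camera, adjusted p = 0.000626, and adjusted p = 0.320 with an estimated correlation).

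Between line 4 and line 1, 8442 genes differed, 3715 higher and 4727 lower in line 4, and 672 by at least 2-fold. The libraries of the lines did not overlap in 8867 genes, which chance gives for 10% of genes. After CYP26A1, at 4.11 ± 0.08, the largest differences toward line 4 were in PAPLN, an extracellular matrix protein, at 3.63 ± 0.17, OTX2, at 3.37 ± 0.14, LHX5, at 3.32 ± 0.19, and ZFP42, at 3.06 ± 0.10. Those toward line 1 were HSPA6, at -7.02 ± 0.17, SPANXB1, at -3.88 ± 0.13, HSPA1A, at -3.40 ± 0.10, and SPANXN3, at -3.36 ± 0.18. Adjusted p for these 9 genes was at most 9.39e-09 by limma. SPANXB1, of a testis-expressed family, was listed at 0 in the 3 wild-type libraries. SPANX genes and the nearly identical HSPA1A and HSPA1B share reads, so these values are uncertain.

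Of the lists, p53 targets were lower in line 4 in 16 of 16 genes (camera, adjusted p = 8.94e-10, and adjusted p = 0.270 with an estimated correlation), stress genes in 13 of 17, with 1 higher (3.21e-06, and 0.253 with an estimated correlation) and proliferation genes in 17 of 22, with 2 higher (0.00102, and 0.520 with an estimated correlation). GDF15, a p53-responsive cytokine, stood at 102 ± 9.54 FPKM in line 1 and 15.5 ± 1.88 in line 4. Higher in line 4 were the forebrain list (0.000626, and 0.320 with an estimated correlation) and the neural progenitor list, in 9 of 14 genes, with 1 lower (0.00936, and 0.551 with an estimated correlation). Pluripotency genes were higher in 7 of 12 and lower in 3, among them NANOG and POU5F1, and WNT genes were higher in 10 of 19 and lower in 3 (0.0184 each, and 0.320 and 0.519 with an estimated correlation). Hypoxia and glycolysis genes were higher in 10 of 19 and lower in 3 (0.0310, and 0.710 with an estimated correlation), and GAPDH, chosen after its values were seen, turned from 0.40 to -0.28 with quantile normalization. Adjusted over the list alone, these 8 lists gave the same numbers.

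**Figure D4:**
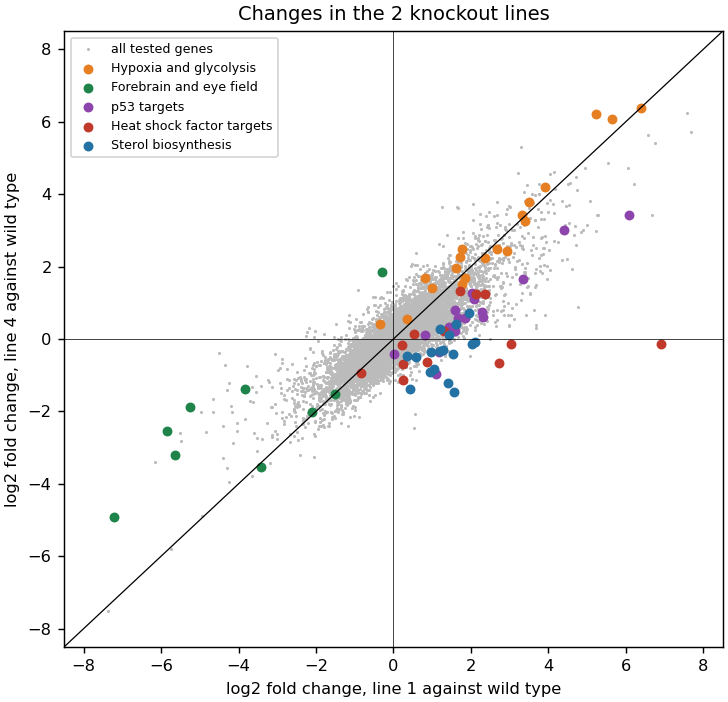
Log2 fold change against wild type of tested genes in line 1 (horizontal) and line 4 (vertical), with 5 gene lists coloured and the diagonal marking equal change; the heat shock and sterol lists were chosen after the data were seen, and Y-linked genes are not drawn. Hypoxia genes lie near the diagonal, and p53 targets lie below it.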

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

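The effects of the knockout lines were compared by the limma test of line 4 against line 1, and named genes are given here where that test passed with at least a 2-fold difference. All tests of explanations below, and the counts of other splits, were written down only after the results they bear on had been seen. Groups of 3 libraries are too small for a test of single outlying libraries.

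The lines differed in 8442 genes and, at the preset correlation, in 8 lists, of which none passed with an estimated correlation (lowest adjusted p = 0.253). The list medians, line 4 minus line 1, were 2.30 for forebrain and eye field, 0.69 for pluripotency, 0.44 for neural progenitor, 0.27 for hypoxia and glycolysis, 0.21 for WNT, -0.40 for proliferation, -1.09 for stress and -1.31 for p53 targets. Of 88 named genes reported here, 31 differed by at least 2-fold, 16 higher and 15 lower in line 4. Neural and anterior genes higher in line 4 were OTX2 (3.37), LHX5 (3.32), SOX21 (2.96), LMO1 (2.75), SEZ6 (2.68), SIX3 (2.43), FEZF1 (2.30) and MAP2 (1.26). CYP26A1 (4.11), PAPLN (3.63), ZFP42 (3.06), FZD5 (2.10), FRZB (2.0), SFRP1 (1.93), SALL4 (1.17) and ZEB2 (1.11) were also higher there. Stress and p53 genes lower in line 4 were HSPA6 (-7.02), HSPA1A (-3.40), GDF15 (-2.65), TRIB3 (-1.83), BTG2 (-1.70), ATF3 (-1.58) and CDKN1A (-1.41). The other genes lower in line 4 were SPANXB1 (-3.88), SPANXN3 (-3.36), ANXA1 (-1.97), NPPB (-1.35), TAGLN (-1.34), ID2 (-1.22), NANOG (-1.10) and ETS1 (-1.02).

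Of 9 forebrain genes, 9 fell in line 1 and 8 in line 4, where FEZF2 rose, and of 19 hypoxia genes 18 rose in line 1, where EGLN3 fell, and 19 in line 4. With an estimated correlation, adjusted p was 0.123 and 0.269 for the forebrain list and 0.174 and 0.164 for the hypoxia list. Library scaling is argued against, since under TPM, median-of-ratios and quantile scaling the forebrain median stayed at -3.41 or lower while the hypoxia median stayed at 2.19 or higher. A trend with GC content and length is argued against as the whole cause, since the forebrain median minus the median of all genes was -3.39 after correction. Undifferentiated stem cells left in the knockout cultures stay open: of 12 pluripotency genes 5 fell in both lines (ZFP42, SALL4, LIN28A, DNMT3B and VRTN) and 5 rose in both (POU5F1, NANOG, UTF1, DPPA2 and L1TD1), which decides nothing. The oxygen, density or medium of the cultures also stays open, since genotype and culture coincide in all 9 libraries; the hypoxia median of 2.30 and an effect of E2A loss cannot be told apart from such a difference.

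In 6 genes the level was above 10 FPKM in the 3 wild-type libraries and below 1 FPKM in all 6 knockout libraries: OTX1, SMOC1, VPS37B, CHCHD2, PAX6 and LMX1A. A deletion that takes in neighbouring genes is argued against for the set, since the 12 nearest tested neighbours had a median log2 change of -0.13, with quartiles of -0.75 and 0.20 and a lowest value of -1.73. Smaller deletions within a gene were not tested. Silencing in a sub-line shared by both knockout lines, and not caused by the edit, stays open for these 6 genes and cannot be told apart from an effect of E2A loss, because there is 1 wild-type line.

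Sterol biosynthesis genes, a list chosen after the data were seen, rose in 17 of 17 genes in line 1. In line 4 the list had a median of -0.36, with 11 genes lower, 3 higher and 3 not passing, and did not pass (camera, adjusted p = 0.129, and adjusted p = 0.732 with an estimated correlation). A weaker form of the same change in line 4 stays open for the list as a whole, since its members moved both ways there. The 11 lower genes were picked by their direction in line 4, so they cannot test that explanation. Medium or handling that differed between the lines also stays open, since line and handling coincide: the difference of -1.60 cannot be told apart from a difference between the lines themselves.

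Chance was examined by refitting other splits of the libraries. For the mean of both lines, 1 of 100 splits, the real one, gave as many as 10965 genes, and the highest other gave 8751. This argues against chance in how the libraries were divided into groups. For genes changed in both lines, 1 of 100 gave as many as 8314, with 7001 the highest other, which argues the same way. The splits shuffle single libraries, so they cannot exclude chance differences between lines or cultures. Knockout lines 1 and 4 alone differed in 8442 genes. For the number of lists, 16 of 100 splits gave as many as 12, and the highest other also gave 12. Chance cannot be excluded for that number. Other splits can keep part of the real grouping, which also raises their counts, so the tie does not show that chance gave it. For line 1, line 4 and the difference between the lines, the 10 splits are too few for a share under 0.05; the real counts were 10837, 10462 and 8442, each reached by 1 split, and the highest other was 0.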

How the results depend on the processing

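The correction for GC content and length was chosen after the data were seen and covered 12979 of the 13610 tested genes; the other alternatives were fixed before. Requiring at least a 2-fold change lowered the counts by construction, to 2287 for the mean of both lines, 2786 for line 1, 2082 for line 4, 1564 for genes shared by both lines and 672 for line 4 against line 1. The number of lists that passed was 0 with camera and an estimated correlation and 19 with fry, which tests whether a list moves on balance and does not compare it with other genes. Under fry the neuronal list turned from lower to higher, at adjusted p = 0.0228 (its mean was 0.09 and its median -0.66). TBX6, which did not pass, changed sign to 0.028 with median-of-ratios scaling, and ran from -0.094 to 0.0028 when single libraries were left out; the cause was not tested. Total counts of genes stayed within 1.5 times their reported values under the other alternatives. With a mean of at least 5 FPKM, which left 9237 genes to test, the higher genes fell further, to 3011 for the mean of both lines, 3167 for line 1, 2805 for line 4 and 2241 for genes shared by both lines. Among the named genes, MIXL1 did not pass with quantile normalization and TBX6 passed with the GC and length correction. The share of higher genes among the calls for the mean of both lines was 43.5% as deposited, 37.0% with TPM and, with 5419 higher and 5421 lower, near even with median-of-ratios scaling. Among list members called for that mean, WNT4 alone turned sign under a scaling, to -0.01 with quantile normalization. The replicate numbers were not treated as pairs: same-numbered libraries had residual correlations from -0.03 to 0.23, above 0.1 in 4 of 9 pairs. Their mean was 0.11, and 6 of 9 libraries correlated best with their own number, so a partial pairing stays open. The mean of -0.05 for other numbers adds no separate evidence, because the residuals of each group sum to 0. With the replicate block, 11075 genes passed for the mean of both lines. Read depth is unknown, so how far it limits low genes could not be assessed.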

Other observations

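Further gene groups, chosen after the data were seen and tested with camera over 6 lists, moved in the knockout cells. Feedback targets of FGF and ERK signalling rose in 12 of 13 genes, with a median of 3.21 (adjusted p = 1.38e-07, and adjusted p = 0.147 with an estimated correlation). DUSP6, a phosphatase that inactivates ERK, changed by 4.84, DUSP5 by 4.43, and the Sprouty gene SPRY4 by 4.17. Genes of the amino acid response rose in 14 of 14, with a median of 2.52 (adjusted p = 1.03e-09, and adjusted p = 0.115 with an estimated correlation). The amino acid transporter gene SLC7A5 changed by 4.07 and the cystine transporter gene SLC7A11 by 1.86. This list shares ASNS, ATF3, CHAC1, DDIT3 and TRIB3 with the stress list and SESN2 with the p53 list. Metallothioneins, which bind zinc and copper, rose in 7 of 7 (adjusted p = 1.95e-05, and adjusted p = 0.153 with an estimated correlation), with MT2A at 5.21 and MT1X at 3.88. Reads can be shared within this family, so single members are uncertain.

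Heat shock factor targets rose in 12 of 13 genes in line 1, while in line 4 they were higher in 5 and lower in 6. Line 4 was lower than line 1 in 12 of 13 (adjusted p = 1.02e-07, and adjusted p = 0.0718 with an estimated correlation). Over the mean of both lines 8 rose and 3 fell (adjusted p = 0.0135, and 0.248 with an estimated correlation). Sterol biosynthesis genes were lower in line 4 than in line 1 in 17 of 17 (adjusted p = 6.91e-13, and 0.0718 with an estimated correlation), and over the mean of both lines 10 rose and 1 fell (0.00433, and 0.369 with an estimated correlation). HMGCS1, which feeds the mevalonate pathway, changed by 1.41 in line 1 and -1.21 in line 4.

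In 18 genes the wild-type libraries were below 1 FPKM and the 6 knockout libraries above 10 FPKM. PHLDA2, an imprinted gene of placental growth, went from 0.663 FPKM to 43.5 in line 1 and 35.7 in line 4. SFN, an epithelial 14-3-3 protein, went from 0.270 to 83.0 and 32.4, and TAC1, a tachykinin precursor, from 0.320 to 134 and 13.2.

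The imprinted genes NNAT and DLK1 changed by -7.44 and -4.06. A hypothesis formed after these values were seen was a common loss across imprinted genes. The data argue against it, since 7 of 19 tested imprinted genes rose, PHLDA2 by 4.59 and IGF2 by 1.43 among them, and 9 fell (camera, adjusted p = 0.998, and 0.998 with an estimated correlation).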
